A study of Mus musculus with 53 samples.

How the data were processed

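Germinal center (GC) B cells of wild type (WT) littermate mice and of mice with a constitutive deletion of the linker histone genes Hist1h1c and Hist1h1e (H1 DKO) were the material of every library. The labels list 53 samples, of which 43 came with a file. RNA-seq had 4 wild type and 3 H1 DKO libraries. ChIP-seq of H3K27me3, H3K36me2 and H3K27ac had 3 and 3 each, ATAC-seq 4 and 4, 10x single-cell RNA-seq 2 and 2, and CUT&RUN of H3K4me3, H3K9me2 and H3K9me3 1 and 1 each. The Hi-C libraries (2 and 2) and the ChIP input libraries (3 and 3) had no file and were not analysed here. Genotype and replicate number came from the labels. Nothing in the labels says that equal replicate numbers share an animal, a litter or a day. In RNA-seq the Y linked gene Ddx3y was present in wild type 2 and H1 DKO 3 and near 0 in the others, so more than 1 animal stood behind each genotype there, and the 10x titles carry a different number for each library. For the other assays nothing says that replicates of a genotype came from separate animals, and their p-values may measure only technical spread between these samples.

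RNA-seq values were deposited as TPM, 1 list per library, and per the submitters' processing notes STAR and the mm10 build were used. The RNA-seq counting tool and annotation are not given in the sources used here. Library kits per the labels were SMART-Seq v4 for RNA-seq and TrueMicroChip for ChIP-seq. The 10x tables hold UMI counts per gene and barcode with every barcode kept, and per the submitters' processing notes Cell Ranger and Seurat 3.0.2 were used. For H3K27me3 and H3K36me2 the authors deposited called regions with ChIP and control read counts, a p-value, a false discovery rate and a ratio of ChIP over control per region. SICER, BWA and mm10 are named in the submitters' processing notes. For H3K27ac, ATAC-seq and H3K4me3 the deposited region lists hold a score, a fold enrichment, the −log10 of p and q, and a summit offset, and MACS2 is named in the submitters' processing notes with Bowtie2, SAMtools 1.8 and Picard 2.18.11. For H3K9me2 and H3K9me3 the authors deposited SICER regions with a score and no control. Scores and folds per region are the authors' and served here to rank or filter regions within a list. For H3K27me3 and H3K36me2 the folds, with the ChIP and control counts, also gave the ratio of the ChIP and control totals. Relative ChIP depth was that ratio times the control reads per base in called regions, taken where the lists of both marks overlap. The deposited ATAC-seq lists hold chromosomes 1 to 19 and repeat a region once per summit, so repeats were merged. Caller settings are not given in the sources used here.

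RNA-seq genes with TPM of 1 or more in at least 3 libraries were tested with limma 3.58.1 (eBayes with trend) on log2(TPM + 1), and fold changes are on that scale. A gene changed when its Benjamini-Hochberg adjusted p was under 0.05 in a two-sided test. TPM hides the read depth, so whole reads were recovered from ratios of the deposited TPM values between libraries. Of 16875 genes above 0 in at least 2 libraries, 16875 had ratios of whole numbers within a relative tolerance of 1e-12, and 97.65% of values above 0 were recovered. The recovery also gives a length per gene up to a common factor, here called length units. Genes with implied lengths under 100 units numbered 464 and held 38.1% of TPM and 2.46% of recovered reads, and lie mostly on chromosomes 9, X and 15. Their short length raises their TPM per read. The recovered reads were used for depth, for an alternative test with edgeR and for thinning.

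Cells of the 10x libraries were kept with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs. Scrublet scores removed 0.8% per 1000 cells as doublets. Clusters came from Leiden (resolution 0.8) on 15 nearest neighbours over 30 principal components of 2000 variable genes, with scanpy 1.11.5 and leidenalg 0.10.2, leaving out sex genes, immunoglobulin genes and H1 genes. Clusters were named only from fixed markers, needing a mean z of 0.3 and 3 detected markers, and stayed unnamed where the 10 leading genes held more markers of another class. Counts were summed per library over kept B cells, over cycling cells (clusters named S phase or G2/M) and over centrocyte-like cells, and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, two-sided). Shares of cell classes carry 95% Wilson intervals, which cover counting error only, and had no test. Per the labels both wild type 10x libraries came from females and both H1 DKO libraries from males, so sex and genotype cannot be separated there.

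Covered length is the merged length of called regions on chromosomes 1 to 19, X and Y, compared with a two-sided exact permutation test. The smallest p it can give is 0.1 for 3 against 3 and 0.0286 for 4 against 4. A region was specific to a genotype when it was called in every library of that genotype and in no library of the other. For H3K27me3 and H3K36me2 the share of each 50 kb bin under called regions was tested with limma in bins with a mean of at least 5%. The relation of both marks was measured across bins by Spearman correlation. Enrichment in regions called in all 6 libraries, the log2 ratio of deposited ChIP to control counts after scaling by the totals the files imply, was added after seeing the data. Promoters of 2 kb either side of the start were planned for the test of marks at changed genes, but the annotation given, GRCm38, carries no strand. Gene spans with 2 kb on each side were used instead, with two-sided Fisher's exact tests adjusted over 16 tests. A mark was gained or lost when at least 2 more libraries of one genotype covered the span. RNA-seq symbols matched this annotation for 20916 of 23382 genes and through 1 synonym for another 2207, and 10x symbols for 25166 of 31017 and another 592.

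The tests, the thresholds, 26 gene lists and the rule for named genes were fixed before the data were examined. The rule names Hist1h1c, Hist1h1e and the other linker histones. It then names the 10 largest rises and 8 largest falls among changed genes whose libraries do not overlap and whose mean is at least 5 TPM, or 20 CPM in 10x, in the higher genotype. Predicted genes, clones, immunoglobulin and T cell receptor segments and, in 10x, X and Y linked genes were left out. From each list it takes the 4 members with the lowest adjusted p, and for regions or bins the 3 largest gains and losses. Some items this rule names are not reported here. The lists cover linker histones, GC identity, dark zone, light zone, S phase, G2/M, plasma cell, memory precursor, naive and follicular B cell, MHC class II, T cell, macrophage and dendritic cell, neutrophil, erythroid and platelet, stroma and endothelium, pluripotency, blood stem and progenitor cell, developmental transcription factors, Polycomb components, H3K36 enzymes, H3K9 enzymes, interferon, immediate early and stress, p53 targets, sex genes and core histones. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, repeated with an estimated correlation, and in RNA-seq also with fry, which asks whether a list moves 1 way on balance.

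Alternatives covered the pseudocount (0.1), filters, normalization, library weights, DESeq2 1.42.0, cell filters, cluster resolution, stricter region thresholds, equal numbers of regions, bin size, a replicate block and each library left out. Scripts were tested on simulated data. In the RNA-seq simulation limma found 16.7% of genes changed 1.5-fold, 83.7% at 2-fold and 100% at 3-fold, with 8.07% false calls among all calls. In the 10x simulation edgeR found 38% at 1.5-fold and 93.9% at 2-fold, with 4.85% false calls. In the H3K36me2 bin simulation limma found 26% of bins shifted by 0.2 of their length and 90% at 0.3, with 4.24% false calls. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.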

Results

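The data describe mouse GC B cells, the B cells that divide and mutate their antibody genes during an immune response, with and without 2 linker histones. Linker histones (H1) bind the DNA between nucleosomes and compact chromatin. Transcripts were measured by RNA-seq (4 wild type, 3 H1 DKO) and by 10x single-cell RNA-seq (2 and 2). Chromatin was measured by ChIP-seq of H3K27me3, a mark of Polycomb repression, H3K36me2, a mark of open intergenic and genic chromatin, and H3K27ac, a mark of active enhancers and promoters (3 and 3 each). ATAC-seq of accessible DNA (4 and 4) and CUT&RUN of H3K4me3, H3K9me2 and H3K9me3 (1 and 1 each) were also made. Recovered RNA-seq reads were 8.84, 10.5, 9.84 and 12.8 M in wild type 1 to 4 and 10.1, 12.5 and 10.8 M reads in H1 DKO 1 to 3. The 10x libraries held 55.1 and 52.8 M UMIs in wild type 1 and 2 and 67.6 and 70.9 M in H1 DKO 3 and 4. After filtering, 2928, 3412, 5052 and 4349 cells remained. ChIP reads inside called regions were 3.92, 3.53 and 4.05 M (wild type) and 4.64, 3.92 and 3.89 M (H1 DKO) for H3K27me3. For H3K36me2 they were 6.36, 5.77 and 5.03 M (wild type) and 11.6, 9.13 and 11.2 M (H1 DKO). Depth is unknown for the other region lists.

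The deleted genes were examined first, in every RNA-seq and 10x library. Hist1h1c was at 5.95, 8.92, 6.91 and 7.40 TPM in wild type 1 to 4 and at 0.574, 0.897 and 1.06 TPM in H1 DKO 1 to 3. Its mean fell from 7.29 ± 1.24 (SD, n = 4) to 0.843 ± 0.246 (SD, n = 3), a log2 fold change of −2.17 (limma adjusted p = 0.00148). Hist1h1e was at 3.10, 3.23, 2.66 and 3.59 TPM in wild type and at 0, 0.0395 and 0 in H1 DKO, with a log2 fold change of −2.03 (limma adjusted p = 0.000941). In kept B cells of the 10x libraries Hist1h1e was at 112.8 and 94.3 CPM in wild type and 0.195 and 1.21 in H1 DKO. Hist1h1c was at 42.4 and 38.3 in wild type and 4.91 and 4.77 in H1 DKO. Both genes fell in both assays, and each of these libraries sat with the genotype on its label. Libraries of the other assays were not checked in this way.

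Among the other linker histones, H1f0, the variant usually linked to cells that have stopped dividing, rose in both assays. In RNA-seq it rose from 100.4 ± 22.2 TPM (SD, n = 4) to 1110 ± 35.4 (SD, n = 3), 11.1-fold (limma adjusted p = 0.000249). In 10x B cells it rose from 31 ± 1.67 to 538 ± 4.98 CPM (SD, n = 2 each; log2 fold change 4.17, edgeR adjusted p = 4.39e-09). In 10x, H1fx rose from 135 ± 5.18 to 615 ± 141 (log2 fold change 2.24, edgeR adjusted p = 3.39e-05) and Hist1h1b from 131 ± 10.1 to 331 ± 42.4 (edgeR adjusted p = 3.39e-05). Hist1h1a (30.5 to 49.2), Hist1h1d (27.2 to 49.8) and the testis variant Hist1h1t (0.0989 to 1.38) rose there as well, with edgeR adjusted p of 0.00480, 0.000730 and 0.000432. In RNA-seq Hist1h1t was too low to be tested (0.00487 and 0.0573 TPM), and the others did not pass. H1fx was at 4.71 ± 2.63 and 10.7 ± 1.90 TPM (limma adjusted p = 0.179). Hist1h1b was at 29.2 ± 5.59 and 23.5 ± 4.96 TPM (limma adjusted p = 0.398), Hist1h1a at 1.27 and 1.26 and Hist1h1d at 4.03 and 4.06. Of 7 linker histones tested in RNA-seq 1 rose and 2 fell, and adjusted over the list alone 2 rose and 2 fell. The list had a median log2 fold change of −0.02, a mean of 0.02 and a camera direction of down (adjusted p = 0.578). Of 8 tested in 10x 6 rose and 2 fell, and adjusted over the list alone the numbers were equal (camera adjusted p = 4.81e-11; adjusted p = 0.268 with an estimated correlation).

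**Figure D1:**
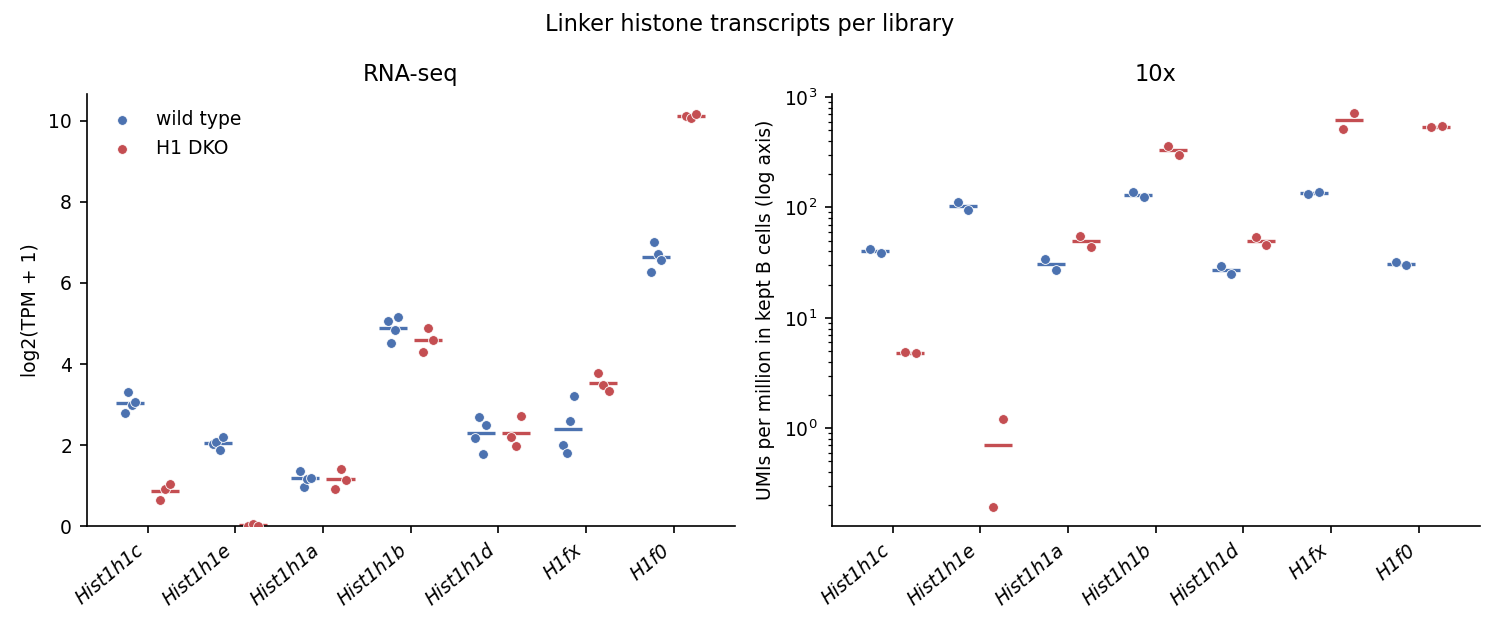
Linker histone transcripts in each library, as log2(TPM + 1) in RNA-seq and as CPM in kept B cells of the 10x libraries on a log axis; points are libraries and bars are means. Hist1h1c and Hist1h1e sit lower and H1f0 higher in every H1 DKO library of both assays.

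The RNA-seq comparison asked which genes differ between the genotypes. Rps6ka6, a kinase of the RSK family, rose from 0 in every wild type library to 183 ± 53.2 TPM (SD, n = 3; limma adjusted p = 3.14e-06). Rnf128, a ubiquitin ligase, rose from 2.18 ± 2.97 to 110 ± 26.8 TPM (limma adjusted p = 0.00641). Tex11, a meiosis gene, rose from 0 to 31.1 ± 23.9 TPM (limma adjusted p = 0.00196). Ptchd1 (0.324 to 28.7 TPM), the collagen lysyl hydroxylase Plod2 (1.85 to 41.4), Rai2 (2.43 to 43.9), Dach2 (1.15 to 18.3), Sytl5 (2.33 to 27) and Hdx (0.304 to 13.4) also rose. Among falls, the inhibitory Fc receptor Fcgr2b went from 187 ± 26.6 (SD, n = 4) to 67.5 ± 35.5 TPM (SD, n = 3; log2 fold change −1.57, limma adjusted p = 0.0472). St14, a membrane protease, fell from 20.7 ± 0.664 to 5.92 ± 2.12 (limma adjusted p = 0.0127). Lyrm4, which acts in iron-sulfur cluster assembly, fell from 17.2 ± 1.84 to 4.85 ± 2.77 (limma adjusted p = 0.0256). Gstt3 (17.7 to 5.97), the urokinase receptor Plaur (19 to 7.98), the protease inhibitor Slpi (41.8 to 18.6) and Fzd6 (15.6 ± 11.4 to 0, mean reads 10.8 to 0) fell too. With edgeR on recovered reads, a test added after seeing the data, the calls of Sytl5 (edgeR adjusted p = 0.0696) and Fcgr2b (0.0619) were lost, and Tex11, Hdx and Fzd6 did not enter it. In all, 188 of 10219 genes changed, 158 higher and 30 lower in H1 DKO, and 1824 passed an unadjusted p of 0.05. Libraries of 2269 genes (22.2%) did not overlap between the genotypes, against 5.71% by chance. Under 1 TPM in wild type 89 of 368 genes rose and 0 fell. Such genes can pass the filter through H1 DKO alone and can then hardly be lower there. At 1 to 5 TPM in wild type 38 rose and 5 fell, at 5 to 20 TPM 18 and 10, and at 20 to 100 TPM 9 and 11. Of 1606 genes above 100 TPM in wild type 4 rose and 4 fell. Quantile normalization moved the median log2 fold change of all genes from 0.01 to −0.09 and gave 86 higher and 34 lower.

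Most of the largest rises rest on few reads. Rps6ka6, Rnf128, Tex11, Ptchd1, Rai2, Dach2, Sytl5 and Hdx lie on the X chromosome and have implied lengths of 84, 87, 55, 74, 78, 71, 75 and 79 units, which raises their TPM per read. Rps6ka6 had 206, 189 and 119 reads in the H1 DKO libraries and 0 in wild type. Genes changed on both TPM and recovered reads with at least 100 mean reads numbered 64 (50 higher, 14 lower), a set chosen after its values were seen. Among them the dystrophin gene Dmd rose from 31.9 ± 22.5 to 254 ± 25.6 TPM (limma adjusted p = 0.0320). Dmd also lies on X, with an implied length of 82 units and a mean of 234.3 reads in H1 DKO. In the same set Lrrn3 rose from 0.939 ± 0.504 to 12.2 ± 1.57 (limma adjusted p = 0.00145), Ranbp17 from 5.89 to 34.5, Rgs4, a regulator of G protein signaling, from 6.20 to 34.9 and Ssbp2 from 1.89 to 10.2. The zinc transporter Slc39a11 fell from 100.1 ± 14.0 to 49.1 ± 2.70 TPM and Gna15, a G protein subunit, from 18.3 to 8.28. Without 1 library the number of changed genes was 60 (wild type 3), 43 (H1 DKO 1), 54 (H1 DKO 2) or 55 (H1 DKO 3). Hist1h1c, Hist1h1e, H1f0, Rps6ka6, Rnf128, Tex11 and Ptchd1 stayed past the threshold without each library in turn. Of 24 named changed genes 10 lost their call without wild type 1 (limma adjusted p up to 0.0868), 3 without wild type 2 (0.0705), 13 without wild type 3 (0.169), 2 without wild type 4 (0.0664), 16 without H1 DKO 1 (0.231), 13 without H1 DKO 2 (0.195) and 14 without H1 DKO 3 (0.191). St14 lost it without wild type 3 alone (0.0553), Fcgr2b without every library but H1 DKO 3, and Hist1h2bc without each in turn, and none changed direction.

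Gene lists of B cell states showed few calls in RNA-seq. The GC identity list (16 tested), dark zone (10), light zone (23), G2/M (20), plasma cell (12), memory precursor (13), naive and follicular (10) and MHC class II (10) lists had 0 members past the limma threshold, also adjusted over the list alone. Pax5, which fixes B cell identity, was at 13.0 ± 3.38 TPM in wild type and 26.9 ± 8.92 in H1 DKO (limma adjusted p = 0.142). The antiapoptotic gene Bcl2 was at 3.97 and 8.27 (limma adjusted p = 0.180), and H2-Aa of MHC class II at 325 ± 30 and 279 ± 12.3. The S phase list was lower as a set (camera adjusted p = 0.0492; adjusted p = 0.831 with an estimated correlation), with 0 of its 20 members changed and 2 of 20 above 0. Its helicase member Mcm5 was at 316 ± 63.8 and 235 ± 16.9 TPM and Gins2 at 26.7 and 19.9. The T cell list (9 tested) and the macrophage and dendritic cell list (13 tested) were lower as sets with the same p (camera adjusted p = 0.0492 each; adjusted p = 0.831 with an estimated correlation). Zap70, a T cell kinase, was at 1.80 and 0.775 TPM, Lat at 17.9 and 10.2, the macrophage receptor Csf1r at 5.20 and 2.66 and Cd68 at 3.85 and 2.60. Adjusted over the list alone 2 T cell markers fell. The S phase, T cell and macrophage lists had a fry adjusted p of 0.334 each. Without wild type 1 or H1 DKO 3 the number of lists past the camera threshold was 0, and without wild type 3 or wild type 4 it was 1. Median and test differed in sign with the mean for G2/M (median −0.07, mean 0.27, down) and Polycomb components (−0.09, 0.10, down). The interferon list (median 0.10, mean 0.02) and the naive and follicular list (0.04, 0.12) had a camera direction of down.

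Other lists held single RNA-seq changes. Of 5 erythroid and platelet genes the carbonic anhydrase Car2 rose from 3.68 ± 1.44 to 10.5 ± 2.12 TPM (limma adjusted p = 0.0473). Of 13 immediate early genes Jun, a subunit of AP-1, rose from 86.0 ± 26.8 to 203 ± 13.2 (limma adjusted p = 0.0363), and adjusted over the list alone 3 rose and 1 fell. Of 11 core histones Hist1h2ac rose (4.98 to 10.8) while Hist1h2bc (2.59 to 1.17) and Hist1h4i (3.85 to 1.38) fell, and adjusted over the list alone 3 rose and 3 fell. On recovered reads the calls of Car2 (edgeR adjusted p = 0.051), Hist1h2ac (0.0554) and Hist1h4i (0.0566) were lost. Of 2 pluripotency genes tested, Klf4 was at 0.359 ± 0.344 and 2.51 ± 1.17 TPM (limma adjusted p = 0.0571), and adjusted over the list alone 1 rose. Of 4 blood stem and progenitor genes 0 passed over all genes, with the cytokine receptor gene Flt3 at 27.5 and 19.9 TPM, and adjusted over the list alone 1 rose and 2 fell. Of 12 H3K36 enzymes Nsd1, which makes H3K36me2, was at 39.2 and 67.7 and Smyd2 at 3.12 and 1.63, and adjusted over the list alone 1 rose and 1 fell. Polycomb components (21 tested), H3K9 enzymes (13), interferon genes (12), p53 targets (11), neutrophil (4) and stromal (1) markers and sex genes (1) had 0 members past the limma threshold, also adjusted over the list alone, and 0 developmental transcription factors were expressed enough to test. The neutrophil granule gene Ltf was at 80.5 ± 84.0 and 17.9 ± 0.796 TPM. Xist, which silences 1 X chromosome in females, was at 12.2 ± 13.0 and 48.2 ± 42.3 TPM, and Y linked Ddx3y was at 39.5 TPM in wild type 2 and 47.8 TPM in H1 DKO 3 and under 1 TPM in the others.

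The 10x comparison asked the same within single cells, with the limit that wild type cells were female and H1 DKO cells male. Xist was at 1097 and 1139 CPM in wild type and 0.744 and 6.66 in H1 DKO, and Y linked Ddx3y at 0.0212 and 0 against 54.8 and 49.2. Besides the linker histones, Parm1 rose from 4.44 ± 0.947 to 24.8 ± 3.98 CPM (SD, n = 2 each; edgeR adjusted p = 2.56e-05). The lamellipodin gene Raph1 (6.98 to 21.3), the histone gene Hist3h2ba (10.6 to 31.2), Anxa5 (9.25 to 26.0), Car2 (9.70 to 26.7), the phosphatase and transcription cofactor Eya1 (9.24 to 25.5) and Crisp3 (18.8 to 50.9) rose. Ly6k rose from 7.16 ± 6.53 to 29.4 ± 14.3 (edgeR adjusted p = 0.0291), a call lost without H1 DKO 3. Hist1h2ab fell from 21.6 ± 1.21 to 3.91 ± 0.736 (log2 fold change −2.41, edgeR adjusted p = 2.56e-05). Hist1h4i (53.4 to 22), the semaphorin receptor Plxnb2 (57.2 ± 2.16 to 25.2 ± 2.56), the tyrosine kinase Fes (28.1 to 13.2), Zfp407 (49.6 to 23.6) and Csprs (31 to 15.7) fell. Of 12776 genes 1418 changed, 1023 higher and 395 lower, 93 of them on X or Y, and 3326 passed an unadjusted p of 0.05. With X and Y left out 1316 changed (945 higher, 371 lower). The count was 303 when cells had to have under 5% mitochondrial UMIs. That limit lies under the median share of every library (6.45% to 7.16%), so it dropped most kept cells, and 10312 genes were tested. A run without 1 library leaves 1 library in a genotype, so the calls it loses rest on the spread of the other genotype alone.

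By list in 10x, 7 of 15 plasma cell genes rose and 0 fell, and adjusted over the list alone the numbers were equal (camera adjusted p = 0.0125; adjusted p = 0.786 with an estimated correlation). They include Tnfrsf17, the BCMA receptor of plasma cells (0.418 ± 0.399 to 3.43 ± 0.920 CPM, edgeR adjusted p = 0.00242), Fkbp11 (2.85 to 7.12), Cd28 (0.317 to 1.58) and Mzb1, a chaperone of antibody assembly (1048 ± 17.8 to 1256 ± 33.5, edgeR adjusted p = 0.0254). The summed B cells held the plasmablast-like cells, at 0.546% and 0.293% of kept cells in wild type and 0.891% and 0.690% in H1 DKO, and sums without them were not tested. Of 16 interferon genes 4 fell and 0 rose, and adjusted over the list alone 5 fell (camera adjusted p = 0.0125; adjusted p = 0.786 with an estimated correlation). Irf7 fell from 30.7 ± 3.16 to 17.6 ± 2.52 (edgeR adjusted p = 0.00568) and Usp18 from 4.83 to 1.80 (edgeR adjusted p = 0.00306). Isg15 fell from 15.1 to 11.1, a call lost without wild type 1 or wild type 2. Of 12 H3K36 enzymes Ash1l (171 ± 9.80 to 118 ± 8.24) and Setd2 (149 to 107) fell, and adjusted over the list alone 3 fell (camera adjusted p = 0.0230, and adjusted p = 0.825 with an estimated correlation). In RNA-seq Ash1l leaned the other way, with a log2 fold change of 1.26 on recovered reads (edgeR adjusted p = 0.293). The S phase list (20 tested, 0 changed, also over the list alone; median log2 fold change −0.16) and the H3K9 enzymes (13 tested, 0 changed, also over the list alone) were lower as sets, with a camera adjusted p of 0.0230 each (adjusted p = 0.849 and adjusted p = 0.786 with an estimated correlation). The MHC class II list was higher with the same camera p (adjusted p = 0.786 with an estimated correlation). There 0 of 10 genes changed over all genes and 5 rose adjusted over the list alone, and H2-Aa was at 2373 ± 157 and 2884 ± 275. The sex gene list had 4 rises and 2 falls of 6 tested, as the labels' sexes imply (camera adjusted p = 9.97e-78; adjusted p = 0.0554 with an estimated correlation).

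Lists without a set call in 10x held scattered members past the edgeR threshold. Of 4 pluripotency genes 3 rose, Klf5 (0.0113 to 0.707 CPM, edgeR adjusted p = 0.00108), Klf4 (0.692 to 1.64) and Lefty1 (23.8 to 33.0). The Klf4 call was lost without wild type 1 and that of Lefty1 without wild type 2. Of 6 blood stem and progenitor genes 2 rose, among them the homeobox gene Meis1 (0.0671 to 0.491). Of 13 p53 targets the cell cycle inhibitor Cdkn1a (1.19 to 2.30), Phlda3 and Tnfrsf10b (0.382 to 1.59) rose. Of 21 Polycomb components Bmi1 rose (5.34 to 8.30) while Mtf2 (140 to 103) and Pcgf6 fell. Of 24 light zone genes Batf rose and Nr4a1 and Traf1 fell. Klf2, a factor of resting B cells, rose from 64.1 ± 13.1 to 113 ± 2.50 (edgeR adjusted p = 0.00232), with Nt5e among 14 memory precursor genes and with Cd55 among 12 naive and follicular genes. Of 15 immediate early genes Jun rose (6.05 ± 1.78 to 19.2 ± 5.17, edgeR adjusted p = 0.00127) and Nr4a1 fell. Of 16 GC identity genes Cd79a rose (2279 to 2692, edgeR adjusted p = 0.0444), of 20 G2/M genes Ccnb2 (147 to 179), and of 10 dark zone genes 0 changed. Of 57 core histones 8 rose, among them Hist1h2bl (1.75 to 8.51), and 7 fell, among them Hist1h4c (9.22 to 1.84), and adjusted over the list alone 8 rose and 9 fell. Among markers of other cells, Cd28 of 6 T cell genes, Adgre1 of 8 macrophage genes and Hbb-bt and Car2 of 4 erythroid genes rose and the macrophage genes Fcer1g and Mpeg1 fell. None of 2 stromal genes or 2 developmental factors changed, and 0 neutrophil genes were expressed enough to test. Adjusted over the list alone the counts of these lists were equal, except for GC identity and G2/M (0 each) and T cells (2 rose, 1 fell). The dark zone list (median log2 fold change 0.02, camera down) and the T cell list (−0.01, up) differed in sign from their test. Of 62 named changed genes 13 lost their call without wild type 1 (such as Cd79a), 11 without wild type 2 (such as Isg15), 4 without H1 DKO 3 (such as Ly6k) and 4 without H1 DKO 4 (such as Fcer1g). Among them were Sec11c, Bmi1, Mtf2, Pcgf6, Batf, Nr4a1, Traf1, Nt5e, Ccnb2, Cdkn1a and Phlda3, and none changed direction.

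In cycling cells 1219 of 11740 genes changed, 816 higher and 403 lower, and in centrocyte-like cells 200 of 9220, 155 higher and 45 lower (edgeR). Adgrl2, an adhesion receptor, rose in cycling cells from 1.73 ± 0.323 to 20.4 ± 4.65 CPM (SD, n = 2 each; edgeR adjusted p = 7.29e-07), with Nrgn (11.7 to 34.5) and Irak1bp1 (7.39 to 21.5), and Pxdc1 fell from 85.1 to 42.9. H1f0 rose in cycling cells (27.3 to 474) and in centrocyte-like cells (19.1 to 364). In centrocyte-like cells, which receive T cell help, Jun (8.05 ± 0.952 to 23.4 ± 3.04), the stress gene Gadd45g (15.1 to 45.3) and the interleukin-3 receptor gene Il3ra (11.1 to 29.5) rose. The DNA repair gene Nbn (20.5 to 9.92), Sh2b2 (24.6 to 12.2) and Idh2 (31.4 to 15.7) fell there. Whether the classes differ from each other was not tested.

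Shares of cell classes in 10x were not tested. S phase cells made up 29.5% of wild type 1 (Wilson interval 27.9 to 31.2) and 25.9% of wild type 2 (24.5 to 27.4), and 24.3% of H1 DKO 3 (23.2 to 25.5) and 20.3% of H1 DKO 4 (19.1 to 21.5). Plasmablast-like cells, the early antibody secreting cells, made up 0.546% and 0.293% against 0.891% and 0.690%, from 16, 10, 45 and 30 cells. G2/M cells were at 8.30% and 8.21% against 9.22% and 8.55%. That share depends on the settings, with means of 14% and 14.6% at a cluster resolution of 1.2, 17.3% and 18.9% with doublets kept, 16.9% and 17.5% with at least 2000 UMIs and 31.8% and 31.3% with cells thinned to 1000 UMIs. An unnamed cluster of 1841 cells was led by histone genes with Nusap1, Top2a and Kif11. Centrocyte-like cells were at 6.69% and 8.09% against 5.94% and 8.55%, and memory or naive cells at 5.02% and 7.59% against 7.68% and 8.92%. Myeloid cells were at 0.683% and 0.557% against 0.416% and 0.483%, and clusters without a name at 49.3% and 49.3% against 51.5% and 52.5%. No cluster was named T cell, erythroid or stromal, and such cells inside other clusters would not be seen. T cell markers scored highest in unnamed clusters of 2219 cells (2 markers detected) and 172 cells (1 marker detected). Phase classes rest on transcripts and also read free RNA.

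RNA-seq and 10x were then set against each other over 9061 genes tested in both. Of 129 genes higher in RNA-seq and 554 higher in 10x, 107 were shared (7.89 by chance), among them H1f0, Rps6ka6, Rnf128, Tex11, Dmd, Lrrn3, Eya1, Car2 and Jun. Of 30 lower in RNA-seq and 301 lower in 10x 16 were shared (0.997 by chance), among them Hist1h1c, Hist1h1e, St14, Gstt3, Lyrm4 and Slc39a11. The opposite genes were Fzd6 (0 to 0.852 CPM in 10x) and Sema5a (1.19 ± 0.306 to 0.16 ± 0.105 TPM in RNA-seq, 1.14 ± 0.365 to 6.48 ± 1.36 CPM in 10x), both named after their values were seen. Of 159 RNA-seq changes 153 (96.2%) had the same sign in 10x, and 95.7% did without sex chromosome genes. Over genes, which are not independent replicates, the fold changes had a Pearson r of 0.40 and a Spearman rho of 0.14.

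**Figure D2:**
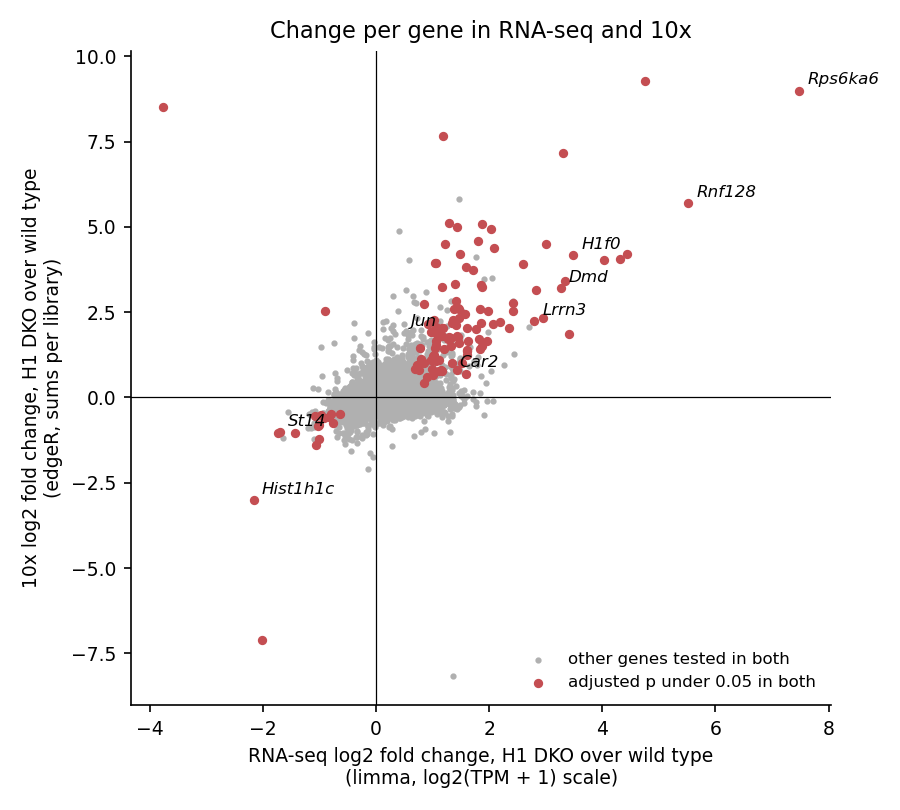
Log2 fold change of H1 DKO over wild type per gene in RNA-seq (limma, log2(TPM + 1) scale) against 10x (edgeR, sums per library); red points have an adjusted p under 0.05 in both. H1f0, Rps6ka6 and Dmd lie at the upper right and Hist1h1c at the lower left.

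The chromatin marks were compared first by the length of genome they cover. H3K27me3 regions covered 169 ± 10.1 Mb (SD, n = 3) in wild type and 176 ± 7.57 Mb in H1 DKO (exact permutation p = 0.4, two-sided). H3K36me2 regions covered 306 ± 24.1 Mb and 399 ± 33.5 Mb, with every H1 DKO library above every wild type library (exact permutation p = 0.1, the smallest that 3 against 3 can give). With the same number of best ranked regions per library the H3K36me2 difference was 33.0 Mb (exact permutation p = 0.6), and H1 DKO libraries were deeper. H3K27ac regions covered 0.681 ± 0.250 Mb and 2.59 ± 0.835 Mb (exact permutation p = 0.1), from 1679, 2976 and 2887 regions in wild type and 7252, 6198 and 9299 in H1 DKO. With equal numbers of regions that difference was 0.377 Mb. ATAC-seq regions covered 39.9 ± 5.25 Mb (SD, n = 4) and 36 ± 15.2 Mb (SD, n = 4; exact permutation p = 0.857). Without H1 DKO 4, which covered 13.6 Mb, the H1 DKO mean was 43.4 Mb and the direction turned (exact permutation p = 0.4).

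**Figure D3:**
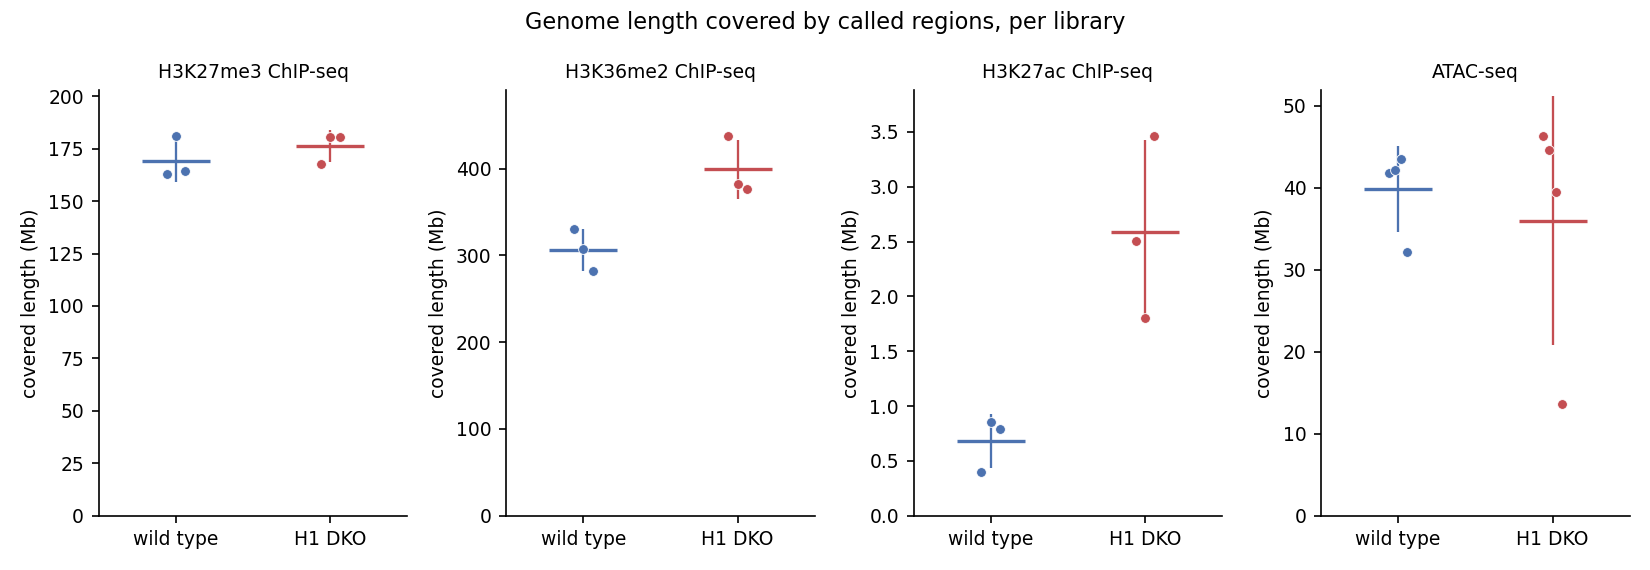
Genome length in Mb covered by called regions in each library of 4 assays; points are libraries, horizontal bars means and vertical bars 1 SD. H3K36me2 and H3K27ac lie higher in every H1 DKO library, and ATAC-seq of H1 DKO 4 lies at 13.6 Mb.

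Broad domains were then tested in 50 kb bins with limma. H3K36me2 rose most over Serpinb9c (chromosome 13, 33100001 to 33150000), from 4.93% ± 8.54 to 99.5% ± 0.924 of the bin (SD, n = 3 each; limma adjusted p = 0.000231). It rose over Map2, a neuronal microtubule gene (chromosome 1, 66350001 to 66400000), from 0% to 90.7% ± 9.02, and over Rasgrf2, a Ras activator (chromosome 13, 91900001 to 91950000), from 0% to 89.1% ± 3.61. It fell most on X, at the H3K27 demethylase gene Kdm6a (18150001 to 18200000), from 63.5% ± 3.40 to 9.73% ± 5.14, over Slc9a7 (20250001 to 20300000), from 66.8% ± 17.8 to 8.27% ± 1.62, and beside Slc9a7 (20300001 to 20350000), from 68.9% to 22.9%. Of 16498 bins 3587 changed, 3526 up and 61 down (98.3% up), and 5569 passed an unadjusted p of 0.05. On X 10 rose and 20 fell. Quantile normalized shares gave 1601 up and 1005 down (61.4% up). Without wild type 3 the number was 2139.

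H3K27me3 rose most over Prss23, a serine protease gene (chromosome 7, 89500001 to 89550000), from 17.7% ± 2.84 to 80.4% ± 10.1 of the bin (SD, n = 3 each; limma adjusted p = 0.00239). It rose beside Parm1 (chromosome 5, 91450001 to 91500000), from 1.2% ± 2.08 to 62.9% ± 14.0, and over Zfp648 (chromosome 1, 154200001 to 154250000), from 14.4% to 75.1%. It fell over Lekr1 (chromosome 3, 65700001 to 65750000), from 63.6% ± 3.27 to 0%, over the kinase gene Cdc42bpa (chromosome 1, 180050001 to 180100000), from 60.3% to 0%, and over Celf2 (chromosome 2, 6800001 to 6850000), an RNA splicing regulator, from 69.6% to 9.87%. Of 14164 bins 3315 changed, 1867 up and 1448 down (56.3% up), and 5465 passed an unadjusted p of 0.05. On X 2 rose and 124 fell. Without wild type 3, H1 DKO 2 or H1 DKO 3 the number was 1553, 1981 or 2168. The share that rose was 46.9% without wild type 1, 48.2% without wild type 3 and 49.9% with the better ranked 50% of regions, so that falls outnumbered rises.

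**Figure D4:**
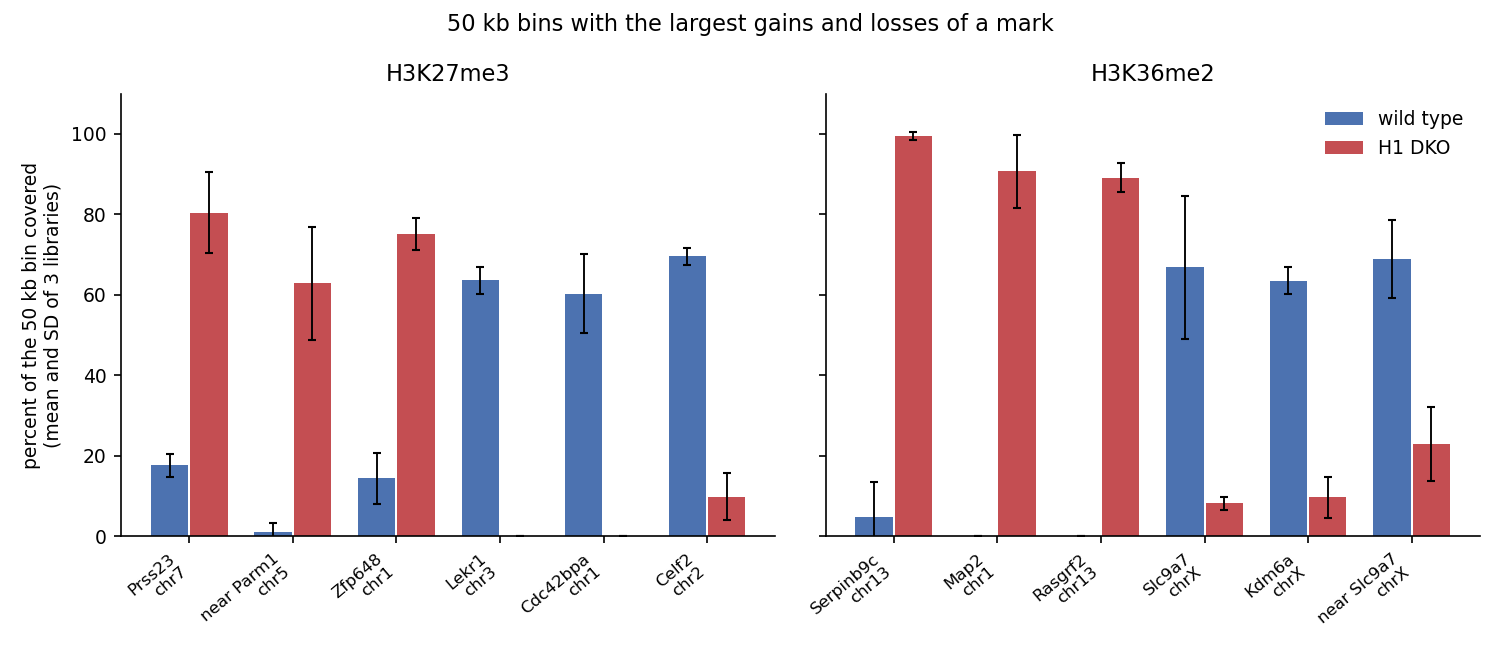
Percent of each 50 kb bin covered by called regions for the bins with the largest gains and losses of H3K27me3 and H3K36me2; bars are means and lines 1 SD of 3 libraries. The Serpinb9c bin goes from 4.93% to 99.5% under H3K36me2 and the Lekr1 bin from 63.6% to 0% under H3K27me3.

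Regions found in every library of 1 genotype and in none of the other were counted next. For H3K36me2 3832 were specific to H1 DKO and 61 to wild type (98.4%), covering 34.7 and 0.509 Mb. The longest lay over Map2 (chromosome 1, 66315401 to 66416000), Rasgrf2 (chromosome 13, 91877801 to 91946000) and Zfp827 (chromosome 8, 79127201 to 79194200). The longest in wild type overlapped Togaram1 (chromosome 12, 64980001 to 64997000) or had Tenm2 (chromosome 11, 37657401 to 37685800) or Stim2 (chromosome 5, 55274001 to 55290600) as nearest gene. With equal numbers of regions the counts were 863 and 239 (78.3%), and without H1 DKO 1 the sum was 6759. For H3K27me3 1212 were specific to H1 DKO and 1678 to wild type (41.9%), and on X 9 and 189. The longest in H1 DKO overlapped Rims2 (chromosome 15, 39388201 to 39410000) and Adgb (chromosome 10, 10380801 to 10401800) or lay nearest Plk2 (chromosome 13, 110640801 to 110666600). Long ones in wild type lay nearest Nampt (chromosome 12, 32600801 to 32628200) and Efnb1 (X, 99288801 to 99314400). The balance turned when called regions had to cover 50% of the merged region (1621 and 1268; 56.1%) or with equal numbers of regions (1516 and 1003; 60.2%), and also without H1 DKO 2 (52.8%) or H1 DKO 3 (52.3%). Without wild type 1 or 2 the sum was 4431 or 4726.

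For H3K27ac 1144 regions were specific to H1 DKO and 0 to wild type, a count without a test. With equal numbers of regions they were 32 and 23 (58.2%), and the sum was 1736 without H1 DKO 1 and 2414 without H1 DKO 2. The longest lay at the B cell factor gene Ebf1 (chromosome 11, 44617963 to 44619446), at Ncoa2 (chromosome 1, 13373203 to 13374573) and nearest Btg2 (chromosome 1, 134064916 to 134066266). For ATAC-seq 57 were specific to H1 DKO and 93 to wild type (38%). The longest overlapped Kcnt2 (chromosome 1, 140308354 to 140309264) and Epha7 (chromosome 4, 28861820 to 28862723) or lay nearest Fstl5 (chromosome 3, 77692597 to 77693535) in H1 DKO. In wild type they lay nearest Laptm4a (chromosome 12, 8906859 to 8907616), Ywhaq (chromosome 12, 21451385 to 21452114) and Dll4 (chromosome 2, 119313796 to 119314487). The ATAC-seq sum of 150 became 282 without wild type 1, 235 without wild type 3, 669 without wild type 4, 381 without H1 DKO 1, 264 without H1 DKO 2, 267 without H1 DKO 3 and 1443 (1346 and 97) without H1 DKO 4. The ATAC-seq balance was 36 to 124 (22.5%) when called regions had to cover 50% of the merged region and 75 to 55 (57.7%) with the better ranked 50% of regions.

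Enrichment over the control inside regions called in all 6 libraries was added after seeing the data. For H3K27me3 (11738 regions) the median fold over control was 3.30, 3.16 and 3.33 in wild type 1 to 3 and 2.39, 2.23 and 2.39 in H1 DKO 1 to 3, 0.716 times as high (exact permutation p = 0.1, the smallest possible). By limma 4507 regions changed, 23 up and 4484 down. After centring each library on its own median 0 changed by limma, with 1607 at an unadjusted p under 0.05. The number was 2646 without wild type 3, 1495 without H1 DKO 1, 0 (4794 unadjusted) without H1 DKO 2 and 2321 without H1 DKO 3. For H3K36me2 (13899 regions) 0 changed by limma, with 1305 at an unadjusted p under 0.05, and the median log2 enrichment was 1.32 ± 0.05 and 1.40 ± 0.07 (SD, n = 3 each; exact permutation p = 0.2).

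The marks were then compared with each other. Across 23362 bins, which are not independent replicates, the change of H3K27me3 and the change of H3K36me2 had a Spearman rho of −0.362 and a Pearson r of −0.301. Of bins that lost at least 10 percent points of H3K27me3, 1404 gained as much H3K36me2 and 1140 did not, and 114 bins gained both. Quantile normalized shares gave a rho of −0.082. In wild type itself the levels of both marks had a rho of −0.419.

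At genes, spans with 2 kb on each side were set against the RNA-seq calls for 154 genes that rose and 30 that fell. H3K36me2 was gained at 23.4% of genes that rose and at 5.77% of other tested genes (two-sided Fisher's exact test, adjusted p = 1.32e-11). H3K27me3 was lost at 13.6% against 6.59% (adjusted p = 0.00661; adjusted p = 0.426 with 5 kb on each side) and gained at 5.19% against 0.93% (adjusted p = 0.000761; adjusted p = 0.0737 when every library of 1 genotype and none of the other had to cover the span). H3K27ac was gained at 5.84% of genes that rose and 28.8% of the others (adjusted p = 1.32e-11). In all, 4 of 16 tests passed, and none of those on genes that fell did. Only a marked span can lose a mark and only a span not yet marked in most libraries can gain it, so the tests were repeated, after seeing the data, on spans that could change, where 2 of 15 passed. There H3K36me2 was gained at 46.2% of genes that rose and 44.5% of the others and H3K27me3 was lost at 18.8% and 21.1% (two-sided Fisher's exact test, adjusted p = 1 each), so that neither passed. H3K27me3 was gained there at 19% against 1.35% (adjusted p = 9.11e-07) and H3K27ac at 5.92% against 35.3% (adjusted p = 4.42e-16). Tests of gains were not matched for expression, and many genes that rose were under 1 TPM in wild type. At that level H3K27ac lay in every wild type library on 0 of 85 genes that rose and 7 of 274 others. H3K27ac lists were longer in every H1 DKO library, at unknown depth, so these gains cannot tell a lack of H3K27ac at genes that rose from low expression. In every wild type library H3K36me2 lay on 40.3% of genes that rose and on 76.7% of the others (adjusted p = 6.78e-21), and among genes under 1 TPM in wild type on 31.8% and 49.3% (adjusted p = 0.0141). In every wild type library H3K27me3 lay on 68.8% of genes that rose and on 24.6% of the others (adjusted p = 3.24e-29). Among genes under 1 TPM in wild type, the comparison was 67.1% against 59.5% (two-sided Fisher's exact test, adjusted p = 0.43). A span counted even where little of it was covered. In genes that rose the median share of the span in wild type was 8.44% under H3K27me3 and 0.63% under H3K36me2. The others had 0% and 39.1%. Genes were not matched for span length in any of these tests, and a longer span is more easily touched. The H1f0 gene (chromosome 15, 79028212 to 79030504) had 94.2% ± 10.1 of its span under H3K27me3 in wild type and 48.6% ± 15.7 in H1 DKO (SD, n = 3 each). Tex11 went from 30.8% ± 9.33 to 0%, but it lies on X, where 124 H3K27me3 bins fell and 2 rose. The tests on gene spans were not repeated without X. Lrrn3 went from 12.5% to 0% under H3K27me3 and from 7.47% ± 0.796 to 83.1% ± 2.52 under H3K36me2, and H3K36me2 over Ssbp2 went from 9.34% to 81.4%, over Ranbp17 from 5.80% to 42.9% and over Plod2 from 0% to 38.3%. Other named rises had no such gain: Rps6ka6, Tex11, Hdx and Rgs4 had 0% under H3K36me2 in both genotypes and Dach2 went from 1.69% to 0.601%, and Rps6ka6, Hdx and Rgs4 had no H3K27me3 in wild type. These spans of single genes had no test.

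CUT&RUN had 1 library per genotype and mark and so no test. H3K4me3, a mark of promoters, covered 10.9 Mb in 19178 regions in wild type and 12.9 Mb in 21804 regions in H1 DKO. H3K9me2, a mark of silent chromatin, covered 339 and 460 Mb. H3K9me3, a mark of constitutive heterochromatin, covered 376 Mb in 103435 regions with a median width of 2799 bases and 548 Mb in 73050 regions with a median width of 5399 bases.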

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

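No test in this part was chosen after its result was seen. In groups of 4 libraries the highest or lowest value was compared with the nearest other value and the range of the group. Of 34 such groups 6 held a value set apart, where chance gives about 1 in 20. Ptchd1 was at 1.30 TPM in wild type 2 and Hdx at 1.22 TPM in the same library, with 0 in the other wild type libraries. Each value was 1 read, and with 0 in all others any read is set apart, so these 2 say nothing about that library. Fcgr2b was at 227 TPM in wild type 3, with 177 TPM as the nearest wild type library. ATAC-seq of wild type 4 covered 32.1 Mb, with 41.8 Mb as the nearest wild type library, and its regions had a median width of 282 bases against 315. ATAC-seq of H1 DKO 4 had a median width of 203 bases, with 308 bases as the nearest H1 DKO library.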

How the results depend on the processing

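Tests chosen after results were seen are edgeR on recovered reads, the enrichment in shared regions and its alternatives, runs on autosomes, the 10x run without X and Y, the false discovery rate limit, thinned cells, spans that could change and the omission of genes of short implied length. Depth limits the RNA-seq result, since most of its rises lie under 5 TPM in wild type. It also limits the H3K27me3 and H3K36me2 results, since H1 DKO libraries were deeper by the estimate from control reads. Of the results that answer a comparison 159 values stayed the same under the alternatives, 65 moved and 2 differences turned direction. Counts have no direction of their own, and the balance of rises and falls behind them turned in 4 alternatives for H3K27me3 regions, 3 for H3K27me3 bins and 2 for ATAC-seq regions. Named single genes kept direction and call 1128 times and lost the call 184 times, and none changed direction. Other values, of gene lists, correlations and genes with reads, stayed the same 20 times, lost the call 16 times and moved 2 times. The cause was not tested for the changes below, except that fewer libraries must share a region, fewer genes enter a stricter filter, and leaving out a library lowers the sample number.

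RNA-seq gave 188 changed genes, and 108 with a pseudocount of 0.1, 313 without a filter, 37 at 5 TPM or more, 120 after quantile normalization, 440 with library weights and 43 to 201 without 1 library. On recovered reads edgeR gave 142. RNA-seq lists past the camera threshold were 3, and 0 with an estimated correlation and 0 to 3 without 1 library. The 10x count of 1418 became 303 under 5% mitochondrial UMIs and 927 to 2722 without 1 library. DESeq2 gave 1220. Replicate numbers did not pair libraries (correlations of RNA-seq residuals −0.0626, 0.115 and 0.269), and with them as a block RNA-seq gave 153 genes and 3 lists and the bins 2718 (H3K27me3) and 3795 (H3K36me2).

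Genotype specific regions under the better ranked 50% numbered 1729 (H3K27me3), 1372 (H3K36me2) and 481 (H3K27ac), and with equal numbers of regions 1102 (H3K36me2), 55 (H3K27ac) and 275 (ATAC-seq). Without 1 library they ranged from 4039 to 4726 (H3K27me3), 4677 to 6759 (H3K36me2), 1204 to 2414 (H3K27ac) and 218 to 1443 (ATAC-seq). Changed bins under the better ranked 50% numbered 1770 (H3K27me3) and 1311 (H3K36me2), and without 1 library 1553 to 2346 and 2139 to 3736. H3K27me3 enrichment changed in 0 shared regions after centring (limma, 1607 unadjusted) and in 0 to 3587 without 1 library, 0 (4794 unadjusted) being without H1 DKO 2.

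The difference in covered length with equal numbers of regions was 17.2 Mb (H3K27me3), 33.0 Mb (H3K36me2) and 0.377 Mb (H3K27ac), and 1.24 Mb for H3K27ac with the better ranked 50%. For ATAC-seq it was −7.36 to 3.55 Mb without 1 library, turning positive without H1 DKO 4. For H3K4me3 it was 1.26 Mb with equal numbers of regions. The rho between both marks was −0.229 in 10 kb bins, −0.393 in 100 kb bins, −0.082 after quantile normalization, −0.384 on autosomes and −0.370 to −0.312 without 1 library. Tests of marks at gene spans that passed numbered 4, and 2 on spans that could change. Differences in cell shares that moved by more than 1 SD within genotypes or turned, in percent points, were 1.62 for G2/M with doublets kept and −0.495 with cells thinned to 1000 UMIs, −0.259 (resolution 1.2) and −0.00971 (thinned) for myeloid cells, and 4.21, 4.47, 4.44 and 5.52 for unnamed clusters under the alternatives. The others moved less, such as from 2 to 0.795 for memory or naive cells and from −0.146 to −0.787 for centrocyte-like cells when thinned.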

Other observations

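Tests chosen after the result was seen are those of depth and sex for the H3K36me2 length, those of sex, depth and a genome-wide loss for H3K27me3 on X, and the counts of genes with reads, of silent genes with a read and of shared regions with changed enrichment. A small 10x cluster without a name (172 cells) was led by the interferon genes Ifit3, Isg15, Usp18 and Irf7. It made up 1.61% of wild type 1 and 1.82% of wild type 2, and 0.554% of H1 DKO 3 and 0.805% of H1 DKO 4. The MHC class II list had a median log2 fold change of −0.22 in RNA-seq and 0.23 in 10x, and its member Cd74 was at 2132 ± 296 and 1755 ± 89.2 TPM in RNA-seq. Median log2 fold changes in RNA-seq and 10x also had opposite signs for H3K36 enzymes (0.273 and −0.192) and H3K9 enzymes (0.267 and −0.165). The same held for plasma cell (−0.136 and 0.274) and interferon genes (0.0991 and −0.342), while the S phase list was below 0 in both (−0.205 and −0.16). Whether the assays differ in these lists was not tested.

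For RNA-seq the real split gave 188 changed genes and the highest of the others 2, so that 1 of 35 splits was as large. That is the smallest share this design allows, and it argues against chance without excluding it. For ATAC-seq regions 14 of 35 splits were as large as the real 150, and the highest other gave 806. That split set wild type 1, wild type 4, H1 DKO 3 and H1 DKO 4 apart, and 804 of its regions lay on the side without H1 DKO 4, the library with the least covered length. The libraries set apart covered 41.8, 32.1, 39.5 and 13.6 Mb and the others 42.1 to 46.3 Mb, so that split follows covered length and not genotype. What set the covered lengths was not tested. For 3 against 3 the splits are too few to tell, and 1 of 10 was as large in each of these results. The real and highest other values were 2890 and 303 (H3K27me3 regions), 3893 and 221 (H3K36me2 regions), 1144 and 161 (H3K27ac regions), 3315 and 0 (H3K27me3 bins), 3587 and 0 (H3K36me2 bins) and 4507 and 52 (H3K27me3 enrichment). For H3K36me2 enrichment all 10 of 10 splits gave at least the real 0, and the highest other gave 1.

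More genes had reads in H1 DKO. With every RNA-seq library thinned to the smallest, 13325.5 ± 573 genes (SD, n = 4) had a read in wild type and 15194 ± 517 (SD, n = 3) in H1 DKO (two-sided exact permutation p = 0.0286, the smallest possible), and the lowest H1 DKO library exceeded the highest wild type library by 655 genes, which argues against depth. Olfactory and vomeronasal receptor genes took 3.62 and 21.2 RPM, with the lowest H1 DKO at 2.21 times the highest wild type library. Marker reads of T cells (0.732-fold), macrophages (0.702-fold), neutrophils (0.259-fold), erythroid cells (1.43-fold) and stroma (1.1-fold) stayed below that. This argues against these cell types as the source of the receptor reads. It does not reach the other silent genes, since all silent genes took 110.8 and 699.5 RPM, nor cell types outside these lists. The 10x libraries showed the same order by 610 genes after thinning, which argues against a feature of the RNA-seq libraries alone, though sex goes with genotype there. Genomic DNA cannot be told apart. The gain in the share of silent genes with a read was, on receptor genes, 0.443 times that on the others. Per H1 DKO library it was 0.281 to 0.529, on either side of the bound of 0.5. The gain per length was 0.588 times on genes with recovered reads, a set chosen by having reads. Over every silent gene it was 0.161 times, which had to assume a length for 1305 of 1456 receptor genes. A wider leak of silent genes without H1 remains a hypothesis.

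H3K36me2 covered more genome in every H1 DKO library. Sex of the animals, which the labels do not give for these libraries, stays open, since leaving out X and Y (at most 2.66 Mb) could not close a gap of 46.5 Mb, and the 1.15 times left on autosomes decides nothing. Depth stays open, since the shallowest H1 DKO library was 1.31 times as deep as the deepest wild type library and equal numbers of regions gave 33.0 Mb with overlapping genotypes. A spread of H3K36me2 without H1 may add to it, and these libraries cannot show how much.

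H3K27me3 covered 3.64 ± 1.6 Mb (SD, n = 3) of X in wild type and 0.954 ± 0.0621 Mb in H1 DKO (two-sided exact permutation p = 0.1, the smallest possible). Depth is argued against, since H1 DKO libraries were 1.49 times as deep on average. A loss over the whole genome stays open. Autosomes had 1.06 times the covered length, but in libraries that this estimate puts deeper. In autosomal regions called in all 6 libraries, 4502 of 4526 changed regions had lower enrichment in H1 DKO (limma). That enrichment is a ratio to the control, which may itself have moved. Sex of the animals, through the H3K27me3 of the inactive X in females, cannot be told apart from genotype. Control reads on X over autosomes separated the genotypes in H3K36me2 regions (highest H1 DKO over lowest wild type 0.942) and not in H3K27me3 regions (1.02), several measures having been tried. The ratios were 0.79 to 0.845 in wild type and 0.644 to 0.744 in H1 DKO in H3K36me2 regions. In H3K27me3 regions they were 0.804 to 0.904 and 0.733 to 0.819. Shifts of this size do not give the sex of any library. A loss on X through H1 itself was not tested.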
